A study of Mus musculus with 24 samples.

How the data were processed

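Total RNA was measured in 12 replicates, 3 each of CT-BM, L-1210, M1 and PYS. Per the labels, the authors extracted total RNA with a mirVana kit, reverse transcribed and preamplified it, ran it on TaqMan rodent miRNA cards A and B for 40 cycles on an Applied Biosystems 7900HT, and grew the lines to passage 3. Each replicate title stands on a pair of GEO samples, 24 in all, one for each card. The 1 deposited table holds, per the file headers, the Ct of each well (PCR cycles, not normalized to the endogenous controls) and the Ct Avg, the mean Ct over the wells of one assay on one card, also in PCR cycles and not normalized. The labels state neither the software version nor a detection limit. No column of values per sample was left unused (0 columns).

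The table was read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6. It held 8969 wells of the 9216 on 24 full cards, so 247 (2.68%) were absent, and 4334 were undetermined. Of the 4635 that amplified, from Ct 5.73 to 37.0, 15 had a Ct over 35. Ct Avg was checked as the mean of its wells within 0.001 cycles in 7000 of 7000 values, and wells of an assay repeated on a card were averaged. Undetermined wells and Ct over 35 were set to 35 and counted as not detected. Of 2336 combinations of miRNA assay and group, 2172 had all 3 replicates and 164 had 2, and 5 had both amplified and undetermined replicates. On card B the median SD between repeat wells was 0.108 cycles over 849 sets of wells. The number of replicates and this spread limit the precision, and no read depth applies. Assay names starting with mmu (517) and rno (67) were kept apart.

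Delta Ct was the Ct minus the mean Ct of MammU6, snoRNA135 and snoRNA202, the controls that the design text names, on the same card of the same replicate. The negative delta Ct was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 4 group means, all 12 replicates). An assay entered a comparison if every replicate of at least 1 of its groups was detected. A change was called at a Benjamini-Hochberg adjusted p under 0.05, over the assays tested in that comparison, and a fold of at least 2. Folds against a group with no detected replicate are lower bounds at the Ct limit and are written as at least that many fold. The comparisons were each line with CT-BM, L-1210 with M1, and PYS with the mean of the 2 leukaemia lines. Shares of detected assays were compared with exact two-sided permutation tests (SciPy 1.17.1), and figures were drawn with matplotlib 3.10.9.

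The groups, comparisons, 17 lists of miRNAs, naming rule and most alternatives were fixed before the data were examined. The lists were blood lineage, erythroid, miR-181 family, miR-17-92 cluster and paralogs, miR-290 to miR-295 cluster, miR-302-367 cluster, let-7 family, Dlk1-Dio3 locus, Sfmbt2 locus, epithelial, mesenchymal and stromal, endothelial, miR-34 family, miR-15 and miR-16 family, the miR-23, miR-24 and miR-27 clusters, muscle, liver, neuron and pancreas markers, and an X-linked germline cluster. Lists with at least 3 tested members were tested with limma's camera (preset correlation 0.01, Benjamini-Hochberg over lists and the 5 comparisons), beside camera with an estimated correlation and fry. Absent replicates were filled with the group mean for these list tests alone. The rule named the 10 largest increases and 10 largest decreases among called assays detected in every replicate of both groups with groups that do not overlap, the 3 largest bounds in each direction, and up to 4 members of each list by moderated t in each comparison with CT-BM, and the 5 largest in each direction between lines. The text gives a selection of the assays so named. The few assays outside it, given as examples of shared or opposite changes, of sets detected in 1 group or of neighbouring genes, were chosen after their values were seen.

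Alternatives were MammU6, snoRNA135 or snoRNA202 alone, the mean of assays detected in all 12 replicates, quantile normalization, Ct limits of 32 and 40, no filter or a filter for detection in all 12 replicates, a fit of only the groups compared, robust and trended eBayes, no fold minimum, limma's treat against a 2-fold change, replicate number as a block, each card alone, and leaving out each replicate in turn. Added after seeing the data were snoRNA135 and snoRNA202 without MammU6, the 3 controls with U87, only assays present in all 12 replicates, and only assays detected in every replicate of the groups compared. Calls of PYS against each leukaemia line by itself, fitted over the assays tested in each pair, were also counted after seeing the data. Counts shared by the 3 lines were set beside 100 simulations of unchanged groups. Genome positions of miRNA genes came from mouse assembly GRCm38.p6 by gene name and served only to find neighbouring genes. The pipeline was tested on simulated data with 301 assays tested and 30 changed per fold size. Of these, 36.7% to 56.7% were called at a true 2-fold change, 90.0% to 100% at 4-fold and 96.7% to 100% at 8-fold, and 1 to 3 of 211 unchanged assays were called. In the simulated lines left unchanged, 0 of 22 lists passed. The simulated noise was independent between assays, so this count does not test false calls of lists whose members vary together.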

Results

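MicroRNA levels were measured by quantitative reverse-transcription PCR on TaqMan low density arrays in 4 groups of mouse cells with 3 replicates each. CT-BM was primary bone marrow, flushed from femur and tibia per the design text. The growth protocol given for it describes suspension culture and the series title calls the cells stem cells, so which state was measured is not known, and this limits the meaning of every comparison with CT-BM. L-1210 is a lymphocytic leukaemia line, M1 a myeloid leukaemia line and PYS a teratocarcinoma line with an epithelial-like, adherent form. Each replicate was run on card A and card B, which together held 584 miRNA assays and 7 control assays. The table held 8969 wells, and 367 to 380 wells were present per card run, of 384 on a full card. A well reports the threshold cycle (Ct), which falls by 1 for each doubling of template, and 48.3% of wells did not amplify. Depth in the sense of read counts does not apply, and a Ct limit of 35 cycles sets the lowest level that counted as detected. Levels are given as the negative delta Ct, on a log2 scale, relative to the mean of MammU6, snoRNA135 and snoRNA202 on the same card of the same replicate. The median SD of an assay between replicates on this scale was 0.24 in CT-BM, 0.38 in L-1210, 0.30 in M1 and 0.28 in PYS. The labels do not say that replicates are separate cultures or animals, so every p-value measures only the spread between these samples, which may be technical.

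All 4 groups shared a core of abundant miRNAs, and each had a set of its own. In every replicate of every group 204 assays were detected, and 204 were detected in none. CT-BM detected 51.7% ± 0.852 of its assays (SD, n = 3), L-1210 48.6% ± 0.748, M1 44.7% ± 0.383 and PYS 53.8% ± 0.44. For each line against CT-BM the exact two-sided permutation p was 0.1, the smallest that 3 against 3 can give. The most abundant miRNA in CT-BM was miR-223, known from granulocytes, at a mean Ct of 13.5 ± 0.375 (SD, n = 3). Relative to the controls of the same card, the highest in L-1210 and in PYS was miR-19b, of the growth-promoting miR-17-92 group, and in M1 miR-191. In L-1210, miR-709 and miR-466d-3p on card B had an earlier mean Ct than miR-19b on card A (13.9 and 14.1 against 14.3). Detected in every replicate of CT-BM and in no other group were 15 assays, among them the erythroid miR-486, the neuronal miR-124, and miR-143 and miR-214, known from smooth muscle and other mesenchymal cells. PYS alone detected 37 assays, among them 7 assays of the miR-290 to miR-293 hairpins and 5 of the miR-302 hairpins. L-1210 alone detected 8 assays, including miR-297a*, miR-297c and miR-669a of the Sfmbt2 locus, and M1 alone detected 5.

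The control RNAs themselves moved between groups, which sets a limit on all fold changes. On card A, snoRNA202 came up earlier than in CT-BM by 2.64 cycles in L-1210, 2.67 in M1 and 1.53 in PYS. MammU6 came up 0.74 cycles later in L-1210 and 0.567 later in PYS, and 2.17 earlier in M1, beside SDs between replicates of 0.117 to 0.641 cycles. On card B, snoRNA202 came up 3.18 cycles earlier in L-1210, 2.59 in M1 and 2.09 in PYS, and MammU6 0.498 later, 0.784 earlier and 0.78 later, so its shift in M1 was far smaller there. In replicate 2 of M1 the MammU6 wells on card A spread over 3.23 cycles. Scaling by MammU6 alone, snoRNA135 alone, snoRNA202 alone, the mean of assays detected in all 12 replicates, or quantiles moved the median log2 change against CT-BM. The shifts were, in that order, 1.87, -0.23, -1.65, 0.96 and 1.24 for L-1210; 0.58, 0.05, -0.44, 0.50 and 1.06 for M1; and 1.76, -0.92, -0.59, 0.60 and 0.37 for PYS. The plant assay ath-miR159a did not amplify in any well of any group.

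**Figure D1:**
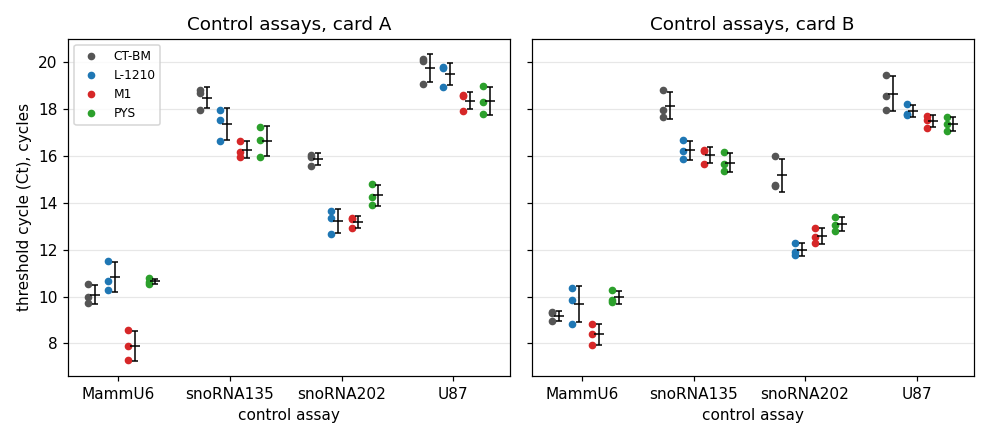
Ct (PCR cycles) of the control RNAs by group and card, where points are replicates and bars are the mean ± SD of 3 replicates. On card A, snoRNA202 sits 2.64 cycles lower in L-1210 than in CT-BM while MammU6 sits 0.74 cycles higher.

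The comparison of L-1210 with CT-BM asks how miRNA levels in lymphocytic leukaemia cells differ from those in primary bone marrow. Of 8 blood-lineage miRNAs 7 were lower and 1 higher in the line, and the list did not pass (camera adjusted p = 0.186). With MammU6 alone and with the mean of common assays 4 of them were lower. The granulocyte miRNA miR-223 was 13101-fold lower (log2 fold change -13.68 ± 0.28, SE, n = 3 against 3), and miR-150, abundant in mature lymphocytes, was 1750-fold lower (-10.77 ± 0.23). The brain-enriched miR-9 was 480-fold higher (8.91 ± 0.54) and its opposite strand miR-9* 454-fold higher, while the pancreatic-islet miRNA miR-375 was 15.1-fold higher. From the Hox gene clusters, miR-196b was 5048-fold lower, and miR-222, from a pair of neighbouring X-linked miRNAs, was 16904-fold lower. The miRNAs of the Sfmbt2 locus, a large intronic cluster, were the one fixed list past the threshold.

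Of the 12 Sfmbt2 assays tested against CT-BM in L-1210, 9 rose, 0 fell and 3 did not pass (camera adjusted p = 0.000115, and adjusted p = 0.309 with an estimated correlation). With MammU6 alone 12 rose, and with snoRNA202 alone 9 rose and 3 fell. Within that locus miR-467c was 27.1-fold and miR-467b 26.2-fold higher, and miR-297a*, not detected in CT-BM, was at least 18052-fold higher. That list passed in 28 of 29 settings of scaling, filter, fit and replicates, the main one included (camera adjusted p 7.68e-07 to 0.97). The imprinted Dlk1-Dio3 locus had 0 higher, 14 lower and 2 not passing of 16 (adjusted p = 0.0607), although with MammU6 alone 8 were lower, and with quantiles 5 higher and 4 lower. In that locus miR-136 was 35.5-fold and miR-434-3p 23.8-fold lower. All 6 assays of the miR-15 and miR-16 family, which restrains the cell cycle, fell (adjusted p = 0.102), though with MammU6 alone 3 fell, and with the mean of common assays and with quantiles 4. Of these miR-16 was 42.9-fold lower. Of mesenchymal and stromal miRNAs 2 of 10 rose and 7 fell (adjusted p = 0.186), with miR-145 at least 27954-fold lower. Among markers of other lineages, where miR-9 and miR-375 were higher, erythroid miR-451 was at least 38139-fold lower, endothelial miR-126-3p 8.74-fold lower and the muscle miRNA miR-133a 934-fold lower. Both erythroid, both endothelial and both miR-181 assays fell, lists too short to test, but with MammU6 alone 1 endothelial and 0 miR-181 assays passed, and with the mean of common assays 1 of each.

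Among the remaining lists in L-1210, the let-7 family had 1 of 8 higher (adjusted p = 0.186), but 8 with MammU6 alone, 6 with the mean of common assays and 6 with quantiles, and with snoRNA202 alone 1 higher and 4 lower. The 1 higher with the 3 controls was let-7a, not detected in CT-BM, where let-7f had a mean Ct of 22.9. The miR-34 family, p53 targets, had 3 of 4 higher (adjusted p = 0.186), but 4 with MammU6 alone, 2 higher and 1 lower with snoRNA135 alone, and 0 higher and 1 lower with snoRNA202 alone. The miR-17-92 group had 1 higher and 1 lower of 12 (adjusted p = 0.365), a count that rested on the scaling. With MammU6 alone 10 were higher, with the mean of common assays 8 and with quantiles 7, and with snoRNA202 alone 1 was higher and 11 lower. Likewise the miR-23, miR-24 and miR-27 clusters had 0 of 4 called (adjusted p = 0.63), but 4 higher with MammU6 alone and with quantiles, 3 higher with the mean of common assays and 4 lower with snoRNA202 alone. Muscle, liver, neuron and pancreas markers had 4 higher and 5 lower of 10 (adjusted p = 0.777), where the median and mean were negative and the test pointed up. Of the miR-290 to miR-295 cluster 0 of 3 rose and 1 fell (adjusted p = 0.959), with a positive median and a negative mean. The majority of its calls turned with MammU6 alone, the mean of common assays and quantiles, and for the lists below turning likewise refers to the majority of calls and not to single assays. Epithelial miRNAs had 1 higher and 3 lower of 7 (adjusted p = 0.959), turning with MammU6 alone and quantiles and even at 3 and 3 with the mean of common assays. Neither of the 2 miR-302-367 assays passed, but with snoRNA202 alone both were lower, with quantiles 1 was higher, and with a Ct limit of 40 2 of 3 were higher. Both X-linked germline assays rose, of which 0 passed with a Ct limit of 32. Adjusted over the list alone, the counts of all 17 lists were the same.

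In the fit (limma, Benjamini-Hochberg over 333 assays), 228 assays changed at an adjusted p under 0.05 and at least 2-fold, 75 higher and 153 lower. For miR-223 the limma adjusted p was 2.71e-13 and for miR-9 3.49e-09, each in the same direction in 3 of 3 replicates. Of the 228 calls, 77 are bounds against a group with no detected replicate. The balance of directions rested on the scaling, with 164 higher and 93 lower by MammU6 alone, 42 and 241 by snoRNA202 alone, 122 and 108 by the mean of common assays, 140 and 107 by quantiles, and 49 and 205 without MammU6.

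M1 against CT-BM asks the same question of myeloid leukaemia cells. Neural miR-9* was 68.8-fold higher (log2 fold change 6.10 ± 0.60, SE, n = 3 against 3), miR-9 64.0-fold higher, and miR-221, which promotes cell cycling, 14.7-fold higher (3.87 ± 0.33). The paralogs miR-125a-5p and miR-125b-5p, the second abundant in blood stem cells, were 2909-fold and 2695-fold lower, and the keratinocyte miRNA miR-203 was 207-fold lower. Granulocyte miR-223 was 11.7-fold lower (-3.55 ± 0.28) and lymphocyte miR-150 52.8-fold lower.

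Of mesenchymal and stromal miRNAs in M1, 8 of 9 fell and 1 did not pass (camera adjusted p = 0.0065, and adjusted p = 0.309 with an estimated correlation). Among them miR-100 was at least 26600-fold lower and miR-145 175-fold lower, and they moved with the erythroid miR-486, at least 6118-fold lower, the muscle miR-133a, at least 381708-fold lower, and the endothelial miR-126-3p, 6.61-fold lower. All 16 assays of the Dlk1-Dio3 locus fell (adjusted p = 0.0021, and adjusted p = 0.309 with an estimated correlation), with miR-411 at least 2040-fold lower, although with quantiles 3 were higher and 9 lower. Of the Sfmbt2 locus 6 of 8 fell and 2 did not pass (adjusted p = 0.0282, and adjusted p = 0.425 with an estimated correlation), with miR-467b at least 7431-fold lower. The miR-17-92 group had 6 higher and 5 not passing of 11 (adjusted p = 0.0158, and adjusted p = 0.537 with an estimated correlation), led by miR-92a at 3.09-fold and miR-19b at 2.70-fold, and with snoRNA202 alone 2 were higher. Over 29 settings, the main one included, the mesenchymal list passed in 28, and the Dlk1-Dio3 locus in 26. The miR-17-92 group passed in 26 and the Sfmbt2 locus in 25. With MammU6 alone the last 2 lists no longer passed (adjusted p = 0.0962 and 0.0642, over ranges of 0.000859 to 0.142 and 0.0073 to 0.526).

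Other lists in M1 did not pass. Blood-lineage miRNAs counted 1 higher, 6 lower and 1 not passing of 8 (adjusted p = 0.413), and the let-7 family 3 higher of 8 (adjusted p = 0.135), of which 2 passed adjusted over the list alone. Adjusted over the list alone, the counts of the other 16 lists were the same. In the miR-15 and miR-16 family 2 of 6 fell (adjusted p = 0.506; 4 with snoRNA202 alone), in the miR-34 family 2 of 3 (adjusted p = 0.498), with miR-34a at least 14503-fold lower, and in the miR-23, miR-24 and miR-27 clusters 2 of 4 rose (adjusted p = 0.407). Epithelial miRNAs had 4 of 7 lower (adjusted p = 0.662) and the miR-302-367 cluster 1 of 3 lower (adjusted p = 0.764), and both turned to higher with quantile scaling, the second also with a Ct limit of 40. Muscle, liver, neuron and pancreas markers had 4 higher and 5 lower of 10 (adjusted p = 0.893), with a negative median and mean and a test that pointed up, and the X-linked germline cluster 3 of 3 higher (adjusted p = 0.0647), of which 1 passed with a Ct limit of 32. Of lists too short to test, 1 of 2 assays of the miR-290 to miR-295 cluster fell, as did 1 of 2 of the miR-181 family (0 with quantiles) and both erythroid and both endothelial assays.

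By limma with Benjamini-Hochberg over 325 assays, 226 assays changed in M1, 82 higher and 144 lower, and the adjusted p was 1.51e-06 for miR-9* and 8.34e-08 for miR-223, each with 3 of 3 replicates in the same direction. Of these calls 84 are bounds. The split was 53 higher and 163 lower by snoRNA202 alone and 136 and 109 by quantiles.

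PYS against CT-BM sets a teratocarcinoma line beside bone marrow. The embryonic stem cell miRNAs of the miR-290 to miR-295 and miR-302-367 clusters were higher in PYS. Among assays measured in both groups miR-302a was 6513-fold higher (log2 fold change 12.67 ± 0.60, SE, n = 3 against 3) and miR-294 1419-fold higher (10.47 ± 0.30). With a Ct limit of 32 no miR-302-367 assay was detected in every CT-BM replicate, so the fold of miR-302a rests on CT-BM signal near the Ct limit. Not detected in CT-BM, miR-291a-3p was at least 106685-fold higher. Granulocyte miR-223 was 458623-fold lower (-18.81 ± 0.28), and miR-142-3p, found in all blood lineages, was 43041-fold lower (-15.39 ± 0.54). In the miR-183 cluster, known from sensory organs, 4 of 4 tested assays were also higher, with miR-182 at 743-fold. This group was chosen after its values were seen and was not tested as a list. The epithelial list, which holds miR-182, miR-96 and miR-183, did not pass (camera adjusted p = 0.718).

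All 11 assays of the miR-290 to miR-295 cluster rose in PYS (camera adjusted p = 0.000115, and adjusted p = 0.309 with an estimated correlation), as did all 8 of the miR-302-367 cluster (adjusted p = 0.0016, and adjusted p = 0.309 with an estimated correlation). Blood-lineage miRNAs counted 1 higher, 7 lower and 1 not passing of 9 (adjusted p = 0.0237, and adjusted p = 0.471 with an estimated correlation), with miR-146a, which damps innate immune signalling, 1340-fold lower. Of the Dlk1-Dio3 locus 14 of 16 fell (adjusted p = 0.000768, and adjusted p = 0.309 with an estimated correlation), with miR-411 86.9-fold lower. All 8 Sfmbt2 assays fell (adjusted p = 0.0034, and adjusted p = 0.309 with an estimated correlation), with miR-467b at least 2787-fold lower. Mesenchymal and stromal miRNAs had 8 of 9 lower (adjusted p = 0.0065, and adjusted p = 0.309 with an estimated correlation), with miR-145 168-fold and miR-199a-3p 65.0-fold lower. Beside them, erythroid miR-451 was 191-fold, muscle miR-133a 1395-fold and endothelial miR-126-3p 10.1-fold lower. Over the settings, the main one included, both stem cell clusters passed in 27 of 27 and the Dlk1-Dio3, Sfmbt2 and mesenchymal lists in 27 of 29. The blood-lineage list passed in 26 of 29 (camera adjusted p 0.0046 to 0.0644).

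The let-7 family, whose members accumulate as cells differentiate, had 5 of 7 lower in PYS (adjusted p = 0.078), with let-7g 52.3-fold lower. The miR-17-92 group had 6 of 11 higher (adjusted p = 0.112), with miR-20a at 4.90-fold, but 11 with MammU6 alone and with the mean of common assays, and 2 with snoRNA135 alone. All 5 X-linked germline assays rose (adjusted p = 0.118), but with a Ct limit of 32 only 3 were tested and 0 passed. Epithelial miRNAs had 4 higher and 3 lower of 9 (adjusted p = 0.718), turning with snoRNA135 alone and snoRNA202 alone, and the miR-15 and miR-16 family 1 higher and 2 lower of 6 (adjusted p = 0.604), turning with MammU6 alone, while with snoRNA135 alone 0 were higher and 5 lower. The miR-34 family had 1 higher and 1 lower of 4 (adjusted p = 0.764), but 3 higher and 1 lower with MammU6 alone. With quantiles, snoRNA135 alone or snoRNA202 alone it had 1 higher and 2 lower. The miR-23, miR-24 and miR-27 clusters had 0 of 4 called (adjusted p = 0.718), but 4 higher with MammU6 alone and 3 higher with the mean of common assays and with quantiles. Muscle, liver, neuron and pancreas markers had 5 higher and 5 lower of 11 (adjusted p = 0.959), with a positive median and a negative mean. Both erythroid, both endothelial and both miR-181 assays fell, although with MammU6 alone 1 endothelial assay passed. Adjusted over the list alone, the counts of all 17 lists in PYS were the same.

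Across 362 assays tested by limma with Benjamini-Hochberg adjustment, 285 changed in PYS, 145 higher and 140 lower, and the adjusted p was 1.09e-08 for miR-302a and 1.72e-14 for miR-223, each with 3 of 3 replicates in the same direction. Bounds make up 106 of these calls. The split was 205 higher and 104 lower by MammU6 alone, 104 and 171 by snoRNA135 alone, and 113 and 170 without MammU6.

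**Figure D2:**
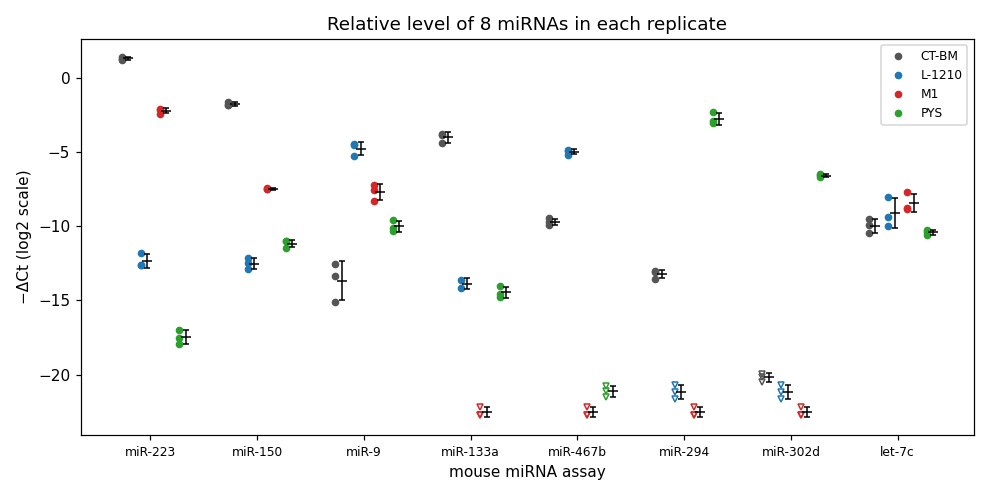
Level of named miRNAs as negative delta Ct (log2 scale) in each replicate by group, where bars are the mean ± SD and open triangles mark groups with no detected replicate. In PYS miR-223 lies 18.81 log2 units below CT-BM and miR-294 10.47 above it.

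**Figure D3:**
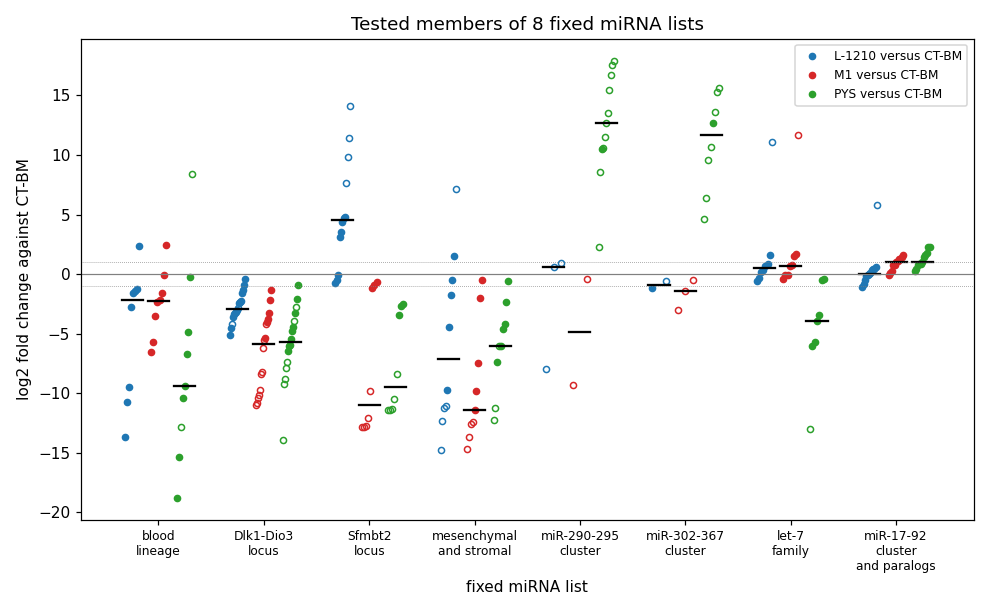
Log2 fold change against CT-BM of each tested member of 8 of the fixed lists, where open circles are bounds or partly detected assays, black bars are medians and dotted lines mark a change of 1. In PYS all 11 assays of the miR-290 to miR-295 cluster and all 8 of the miR-302-367 cluster lie above 1.

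Some miRNAs moved the same way in all 3 lines. Lower in all 3 than in CT-BM were 79 of the 315 assays tested in every comparison, among them miR-223, miR-150, miR-125b-5p and miR-204, and 25 were higher. The higher ones measured in every group included miR-9 (480-fold, 64.0-fold and 12.7-fold in L-1210, M1 and PYS), miR-375 (15.1-fold, 6.31-fold and 81.9-fold) and miR-138, enriched in brain (2.35-fold, 3.69-fold and 111-fold). Those of the 25 not measured in every group had no detected CT-BM replicate, so their folds are bounds. They are all but miR-367 of the 13 assays, treated below, that every line and no CT-BM replicate detected, where failed reactions are a candidate explanation. One of them was rno-miR-532-5p, at least 4019-fold higher in each line, although mmu-miR-532-5p from the same hairpin had a mean Ct of 22.4 in CT-BM. Independent lists of these sizes would share 31.1 lower and 4.18 higher assays. In 100 simulations all groups, CT-BM included, were drawn around the CT-BM means with no change, and at most 0 assays were shared in either direction. With no line changed, a count near 0 is fixed in advance, so the simulations give no baseline for sharing among real changes. Part of the excess may come from the CT-BM samples that all comparisons share, and 3 replicates are too few to split between comparisons. Scaling changed these counts, to 46 lower and 59 higher by MammU6 alone.

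L-1210 against M1 compares the lymphocytic with the myeloid leukaemia line. Myeloid miR-223 was 1122-fold lower in L-1210 (log2 fold change -10.13 ± 0.28, SE, n = 3 against 3). From the Hox clusters, miR-10a was 588-fold higher in L-1210 (9.20 ± 0.27) and miR-196b 15993-fold lower (-13.97 ± 0.46). The largest measured increase was that of miR-31, at 2592-fold, and the largest decrease that of miR-222, at 19361-fold.

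Of the Sfmbt2 locus 9 of 12 were higher in L-1210 than in M1 and 3 did not pass (camera adjusted p = 2.3e-05, and adjusted p = 0.309 with an estimated correlation). In the Dlk1-Dio3 locus 11 of 14 were higher and 3 did not pass (adjusted p = 0.0021, and adjusted p = 0.309 with an estimated correlation), and 12 passed adjusted over the list alone. The Sfmbt2 locus passed in 27 and the Dlk1-Dio3 locus in 26 of 29 settings, the main one included. Blood-lineage miRNAs had 5 of 8 lower (adjusted p = 0.186), but 3 higher and 3 lower with MammU6 alone, the miR-15 and miR-16 family 4 of 5 lower (adjusted p = 0.112) and the miR-34 family 3 of 4 higher (adjusted p = 0.0656). The miR-17-92 group had 1 higher and 6 lower of 12 (adjusted p = 0.186), turning with MammU6 alone, the mean of common assays and quantiles, and the miR-23, miR-24 and miR-27 clusters 2 of 4 lower (adjusted p = 0.764), turning with MammU6 alone. Mesenchymal miRNAs had 4 higher and 1 lower of 7 (adjusted p = 0.206), muscle, liver, neuron and pancreas markers 5 of 8 higher (adjusted p = 0.217), the X-linked germline cluster 1 of 3 lower (adjusted p = 0.461) and the let-7 family 0 of 8 called (adjusted p = 0.81), but 3 higher with MammU6 alone and 7 lower with snoRNA202 alone. Epithelial miRNAs had 1 of 6 higher (adjusted p = 0.709) and the miR-302-367 cluster 1 of 3 (adjusted p = 0.741), of which 0 passed adjusted over the list alone, and both turned with snoRNA202 alone and quantiles. Adjusted over the list alone, 14 of the 16 lists with tested members had the same count. Of short lists, 1 of 2 miR-290 to miR-295 assays was higher, and 0 of 2 passed in the miR-181 family and among endothelial assays. With snoRNA202 alone all 4 of these were lower, and with MammU6 alone both endothelial assays were higher.

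In limma, with Benjamini-Hochberg over 306 assays, 172 differed between the leukaemia lines, 78 higher and 94 lower in L-1210, with an adjusted p of 1.11e-12 for miR-223 and 3 of 3 replicates in that direction. Of these 65 are bounds. The split was 154 higher and 43 lower by MammU6 alone, 61 and 180 by snoRNA202 alone, 107 and 62 by the mean of common assays, and 64 and 136 without MammU6.

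PYS against the mean of the 2 leukaemia lines asks what sets the teratocarcinoma line apart from the blood lines. Stem cell miRNAs were higher in PYS, and let-7 miRNAs lower. Near the detection limit in both leukaemia lines, miR-295 was 233674-fold higher in PYS (log2 fold change 17.83 ± 0.58, SE, n = 3 against 6) and miR-367 73201-fold higher. Blood-wide miR-142-3p was 12292-fold lower (-13.59 ± 0.47) and miR-155, induced in activated lymphocytes and myeloid cells, 544-fold lower (-9.09 ± 0.26).

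All 11 miR-290 to miR-295 assays were higher in PYS than in the leukaemia lines (camera adjusted p = 0.000394, and adjusted p = 0.309 with an estimated correlation), as were all 8 miR-302-367 assays (adjusted p = 0.0034, and adjusted p = 0.336 with an estimated correlation). All 8 let-7 assays were lower (adjusted p = 0.0014, and adjusted p = 0.309 with an estimated correlation), as were all 12 Sfmbt2 assays (adjusted p = 2.3e-05, and adjusted p = 0.309 with an estimated correlation). For 9 of these 12 (miR-467a to miR-467e, miR-297a*, miR-297b-5p, miR-297c and miR-669a) the difference is one from L-1210, since neither PYS nor M1 had a detected replicate. Blood-lineage miRNAs had 2 higher and 7 lower of 9 (adjusted p = 0.0237, and adjusted p = 0.471 with an estimated correlation). Both stem cell clusters passed in 27 of 27 settings, the main one included, let-7 in 29 of 29, and the Sfmbt2 and blood-lineage lists in 27 of 29.

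Lists that did not pass between PYS and the leukaemia lines were more mixed. The Dlk1-Dio3 locus had 2 higher and 6 lower of 14 (adjusted p = 0.132), but 6 and 6 of 15 with a Ct limit of 40, 1 and 3 of 13 with a limit of 32, and 0 and 12 with quantiles. Of the others, the miR-15 and miR-16 family had 4 higher and 1 lower of 6 (adjusted p = 0.662), the epithelial list 4 higher and 2 lower of 9 (adjusted p = 0.764) and the miR-34 family 1 and 1 of 4 (adjusted p = 0.604), with 0 and 2 by quantiles. The miR-17-92 group had 3 higher and 1 lower of 12 (adjusted p = 0.716), turning with snoRNA135 alone, while with MammU6 alone 8 were higher and 1 lower. Mesenchymal miRNAs had 4 higher and 3 lower of 8 (adjusted p = 0.959), with a positive median and mean and a test that pointed down. Muscle, liver, neuron and pancreas markers had 6 higher and 3 lower of 10 (adjusted p = 0.893) and the X-linked germline cluster 3 of 5 higher (adjusted p = 0.564), and all 3 of these lists turned with quantiles. The miR-23, miR-24 and miR-27 clusters had 0 of 4 called (adjusted p = 0.879; 1 higher with MammU6 alone or snoRNA202 alone and 1 lower with snoRNA135 alone), with a positive median and mean and a test that pointed down. Both miR-181 assays were lower, 0 of 2 endothelial assays passed, and the 1 erythroid assay tested was higher. Adjusted over the list alone, the counts of all 17 lists were again the same.

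With limma and Benjamini-Hochberg over 362 assays, 269 differed between PYS and the leukaemia lines, 167 higher and 102 lower, with an adjusted p of 6.68e-12 for miR-142-3p and 3 of 3 PYS replicates in that direction. Of these 101 are bounds. As the 2 lines are averaged, 182 of the 269 were called in the same direction against each line by itself, 39 against L-1210 and not M1, 37 against M1 and not L-1210, and 11 against one line with the opposite call against the other. The split was 126 higher and 132 lower by snoRNA135 alone and 121 and 145 by quantiles.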

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

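The tests of reactions that failed in CT-BM and of later Ct there, both tests of the control RNAs and that of independent loss were chosen after the result was seen, whereas the test of removed replicates and the counts of other splits were set before theirs.

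Opposite changes between lines, each with a direct difference of the lines past the threshold, marked these results. Against CT-BM, 15 assays were higher in L-1210 and lower in M1, and 10 were lower in L-1210 and higher in M1. L-1210 and PYS parted in 11 assays higher in L-1210 and 22 lower, and M1 and PYS in 9 higher in M1 and 23 lower. The Hox-cluster miRNA miR-10a rose in L-1210 (log2 fold change 3.23) and fell in M1 (-5.97), a direct difference of 9.20 ± 0.27 (SE, n = 3 against 3). The reverse held for miR-196b, also from the Hox clusters, at -12.30 in L-1210 and 1.66 in M1. Immune miR-155 rose in L-1210 (2.39) and M1 (2.41) and fell in PYS (-6.69), while miR-182 was -3.98 in M1 (3.83 with quantile normalization) and 9.54 in PYS. The small RNA Y1, a control that no comparison used, came up earlier on card A than in CT-BM by 4.58 cycles in L-1210, 6.10 in M1 and 5.20 in PYS, and on card B none of its 11 CT-BM wells amplified.

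In 13 assays every replicate of each line was detected and none of CT-BM, and failed reactions in CT-BM are a candidate explanation. Of 7 other tested assays of the same hairpins, 5 lay below the bound by more than 4.38 log2 units, the 95th percentile of 167 gaps within hairpins. Those gaps came from assays detected in both groups, whereas the 13 assays were picked for no detection in CT-BM. Wide gaps are thus partly fixed by that choice, so this count cannot decide between failed reactions and other causes. A later Ct of all reactions in CT-BM is argued against, since 12 of the 13 median bounds exceed the largest median delay of 187 common assays, 2.31 cycles, and only mmu-miR-367 does not. Strand choice that differs between bone marrow and the lines stays open, as does the biological difference between these cells, which was not tested. Y1, detected in CT-BM on card A at a mean Ct of 26.6 and not on card B, shows that detection there can differ between cards.

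More calls were lower than higher in both leukaemia lines, 67.1% lower in L-1210 and 63.7% in M1. With the mean of common assays in place of the controls the higher of the 2 shares was 55.7% and the other 47.0%, but centring on the assays draws the shares towards an even balance whatever the cause, so this decides nothing. Without MammU6 the lower of the 2 shares was 70.9% and the other 80.7%, which argues against MammU6 by itself as the source of the lower calls. This is no independent test, because the control Ct values fix its direction. In both leukaemia lines MammU6 moved less towards an earlier Ct than the other 2 controls did, so leaving it out must lower the log2 fold changes. Control RNAs whose level differs between CT-BM and the lines stay open, and so does a true fall of miRNAs in these lines, which was not tested.

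One replicate was absent in 164 combinations of assay and group, and never more than one. Independent loss of wells would leave 3.7 combinations expected to lack at least 2 replicates, with a Poisson probability of 0.025 of none, but it stays open because that absence prompted the test. Under removal of the replicate that disagreed, the remaining pair was predicted to lie closer together than pairs in complete combinations. It lay 1.94 times as far apart (95% interval 1.33 to 2.35), where keeping the closest pair of complete combinations would give 0.357 times. The combinations were not matched for spread, and removal from noisier assays could still leave wide pairs, so this cannot decide on removal. How wells came to be absent stays open, and no biological explanation was tested.

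Regrouping the samples set each count beside those of other groupings. The 10 splits of 3 against 3 are too few for a share under 0.05. In L-1210 against CT-BM the real split gave 228 assays and the highest other 2, with 1 split as large, and 1 list against 2, with 7 as large. M1 gave 226 assays against 1 (1 split as large) and 4 lists against 2 (1 split). PYS gave 285 assays against 1 (1 split) and 6 lists against 4 (1 split). L-1210 against M1 gave 172 assays against 3 (1 split) and 2 lists against 4 (4 splits). For PYS against the leukaemia lines as 1 group, a random grouping of these samples is argued against for assays. The real split gave 198, the highest other 96, and 1 of 84 splits was as large. For lists it is not argued against, with 5 in both and 6 of 84. The highest other split for assays set M1 apart. For the shared counts, 1 of 100 splits of the 12 samples gave as many as 79 assays lower in all 3 lines (highest other 65). As many as 25 higher came in 2 of 100 (highest other 40). These splits shuffle all 4 groups at once, so they cannot tell whether the sharing between lines exceeds chance. As replicates may be technical, no split here speaks to chance between cultures or animals.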

How the results depend on the processing

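The alternatives without MammU6, with U87 added, of assays present in all 12 replicates and of assays detected in every replicate of the groups compared were chosen after the result was seen. Of 255 results of single assays, 190 kept their call, or lack of one, under all 32 settings that gave them a value. In some setting 32 lost the call, 25 gained it and 23 reversed. A result called neither in the main fit nor in the setting counted as kept even where its sign changed. Unless a cause is given, the cause was not tested. Signal near the Ct limit bounds what can be seen: a group with no detected replicate gives only a bound.

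Fewer or more assays tested moved the counts by construction. With no filter on detection 473 assays were called in L-1210, 487 in M1 and 349 between L-1210 and M1. Called lower in all 3 lines were 166, and 3 lists passed in L-1210 and 5 between the leukaemia lines. Assays set to the Ct limit in both groups enter here. Their log2 fold change is only the shift of the control mean between the groups, so calls of such assays do not show a changed miRNA. Where the controls came up earlier in a line, such assays read as lower there. Among assays detected in all 12 replicates 111 changed in L-1210, 117 in M1, 138 in PYS, 95 between L-1210 and M1 and 126 between PYS and the leukaemia lines, with 30 lower and 13 higher in all 3 lines, and 0, 0, 1, 0 and 2 lists passed in these comparisons. Among assays detected in every replicate of the groups compared the counts were 149, 139, 175, 104 and 132, again with 30 lower and 13 higher, and 2 lists passed in L-1210, 2 in M1, 0 between L-1210 and M1 and 2 between PYS and the leukaemia lines. Assays present in all 12 replicates gave 44 lower and 16 higher. Card A alone gave 148 in M1, 112 between L-1210 and M1 and 16 higher in all 3 lines, and card B alone 72, 79, 92, 61 and 88, with 20 lower and 9 higher.

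Scaling moved other counts. By MammU6 alone 2 lists passed in M1, and 46 assays were lower and 59 higher in all 3 lines. Higher in all 3 were 14 by snoRNA202 alone, 50 by the mean of assays detected in all 12 replicates and 54 by quantile normalization. In L-1210, 3 lists passed by that mean, 2 by quantile normalization, 2 with a Ct limit of 40 and 2 in a fit of only the groups compared. Quantile normalization gave 2 lists in M1 and 1 between L-1210 and M1. With a Ct limit of 32 the detected share was 50.8% in CT-BM, 47.1% in L-1210, 43.5% in M1 and 52.0% in PYS, as a stricter limit must lower it. By camera with an estimated correlation 0 lists passed in each of the 5 comparisons, where 1, 2, 2, 3 and 1 had an unadjusted p under 0.05 (L-1210, M1, PYS, L-1210 against M1, PYS against the leukaemia lines), and by fry 10, 12, 13, 10 and 13 passed.

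Leaving out 1 replicate gave 225 to 229 changed assays in L-1210, 215 to 227 in M1, 277 to 289 in PYS, 164 to 182 between L-1210 and M1 and 268 to 274 between PYS and the leukaemia lines, with 75 to 80 lower and 24 to 27 higher in all 3 lines. Lists passing were 1 to 2 in L-1210, 4 to 5 in M1, 6 to 6 in PYS, 2 to 2 between L-1210 and M1 and 5 to 5 between PYS and the leukaemia lines. The count of 2 in L-1210 came without CT-BM replicate 2 and without M1 replicate 1. Replicate numbers do not pair the samples, since same-number residuals correlated at a median r of -0.073 over 18 pairs of samples and 1 of 12 samples matched best with its own number. With replicate number as a block the counts were 229, 226, 283, 173 and 269.

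Reversed log2 fold changes of single assays against CT-BM, for results called in the main fit or in that setting, were these. By MammU6 alone, L-1210 gave miR-93 at 0.64, let-7g at 1.13, miR-34c* at 1.34 and miR-27b at 1.60, and PYS gave miR-34c* at 1.16 and miR-34b-3p at 1.44. By snoRNA202 alone, L-1210 gave miR-92a at -1.04, miR-200a at -0.38, miR-34a at -0.59, miR-27a at -1.20, miR-23b at -1.42 and miR-24 at -1.63. By the mean of assays detected in all 12 replicates, miR-93 was 0.018 in L-1210. By quantile normalization, L-1210 gave miR-367 at 3.02, miR-141 at 1.97 and miR-27b at 1.08, and M1 gave miR-295 at 5.08, miR-302a at 1.13, miR-302b at 5.13, miR-367 at 5.49, miR-182 at 3.83, miR-141 at 4.18 and miR-34b-3p at 1.95. With a Ct limit of 32, miR-34c was -0.73 in L-1210 and miR-470* -0.021 in M1, and with a Ct limit of 40, miR-367 was 4.38 in L-1210, and miR-302b 3.53 and miR-367 4.51 in M1. By quantile normalization 31 of the 1180 calls in the 5 comparisons turned to the opposite call.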

Other observations

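The neighbouring gene groups given first were chosen after their values were seen, whereas the test of neighbouring genes was set before its result.

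Calls in some groups of neighbouring miRNA genes, among them miR-322, let-7e and the miR-182 group from the fixed lists, were counted with no test of each group. In the X-linked group of miR-450b, miR-542, miR-351, miR-503 and miR-322, 7 of 7 tested assays fell in PYS against CT-BM, 5 of 7 in L-1210 and 2 of 7 in M1. In M1, 3 were higher and 1 lower with quantile scaling, and 1 and 1 with the mean of common assays. In L-1210, 1 was higher and 2 lower with MammU6 alone, 1 and 3 with the mean of common assays, and 2 and 3 with quantile scaling. There miR-503, linked to cell-cycle arrest, was 50.1-fold lower in PYS, 53.3-fold lower in L-1210 and 26.3-fold lower in M1. In another X-linked group, of miR-500, miR-501, miR-362, miR-188 and miR-532, 7 of 7 rose in PYS, 5 of 6 in L-1210 (2 higher and 1 lower with snoRNA202 alone) and 2 of 5 in M1, with mmu-miR-532-5p at 8.01-fold, 4.61-fold and 2.54-fold. These counts include miR-500 in each line, which had no detected CT-BM replicate and for which failed reactions are a candidate explanation. In the group of miR-182, miR-96 and miR-183, 4 of 4 rose in PYS, while 1 of 2 fell in L-1210 and 2 of 2 in M1. With quantile scaling 1 was higher and 1 lower in each leukaemia line, as with MammU6 alone in L-1210.

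The pair of miR-221 and miR-222 parted the lines. Both fell in L-1210 and in PYS, with miR-221 not detected in either line, while in M1 miR-221 was 14.7-fold higher and miR-222 differed by a log2 fold change of 0.20 ± 0.36 (SE, n = 3 against 3), which did not pass. The group of miR-99b, let-7e and miR-125a had 3 of 4 assays lower in L-1210 and in M1, while in PYS 3 of 5 rose and let-7e fell. In that group miR-99b was 40.4-fold higher in PYS and at least 3025-fold lower in L-1210. Of miR-191 and miR-425, 3 of 4 assays fell in L-1210 and in PYS and 2 of 4 rose in M1, but with MammU6 alone 1 rose and 0 fell in L-1210, and 1 rose and 1 fell in PYS. With the mean of common assays 0 of these 4 were called in L-1210.

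The hypothesis that neighbouring miRNA genes change together was tested by permuting hairpins. Genes were joined into groups by successive steps under 10 kb and all pairs in a group were taken, so a pair can lie farther apart than 10 kb. There were 113 pairs in 24 groups in L-1210, 63 in 24 in M1 and 77 in 26 in PYS. Each pair counted equally, so large groups weigh most in the result. The median gap between neighbours was 0.91 log2 units in L-1210, 0.81 in M1 and 1.25 in PYS, against 2.26, 1.95 and 3.20 for random pairs. The highest of the 3 adjusted permutation p was 2e-04, from 10000 permutations. Neighbours may share a transcript, and similar sequences that one assay reads from several genes could also narrow the gap, which was not tested. Of 517 mmu assays, 90.3% matched a gene by name.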
